A study of Mus musculus with 7 samples.

How the data were processed

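Total RNA from the somatosensory cortex of 129Sv mice was hybridised to spotted cDNA arrays with 2 channels, per the labels. Each of the 7 arrays paired a mouse given DOI (2,5-dimethoxy-4-iodoamphetamine, a hallucinogen that activates the 5-HT2A serotonin receptor) with a mouse given saline, and tissue was taken 1 h after injection. On 4 arrays the DOI dose was 2 mg/kg and on 3 arrays it was 10 mg/kg. The labels call the 7 pairs independent, and each array was taken as 1 replicate. The array titles carry 2 letters whose meaning is not given; 6 of the 7 arrays share a letter with another, of the other dose too, in 1 case both letters, and all 3 arrays at 10 mg/kg share 1 letter. If they name animals, the arrays are not independent and the p values do not hold as given; the direction of the error was not tested. They name no dye, scanner, background correction or normalization, so these are not given in the sources used here. Replicate numbers were given in accession order and pair nothing. RNA input was 20 µg on 2 mg/kg replicate 3 and 15 µg on the others. Serial numbers in the array titles fall into a first slide series (2 mg/kg replicates 1 and 2) and a second (the remaining 5 arrays), which was treated as a batch.

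The deposited table holds 1 value per spot and array, and the values are log10 intensities of a single channel, not ratios of the channels. Their unit is not stated in the labels and was worked out from the values. Back-transformed to a linear scale, they lay on a smooth curve of whole numbers that differed between arrays: below an intensity of 3000, 9454 of 9455 steps between neighbouring values were whole within 0.1 of a step. The largest value was just under the ceiling of a 16-bit scanner, 65535. The intensity worth 1 step at the low end was between 0.48 and 0.992, and the step at an intensity of 1000 was 1.21 to 2.28 times as large. The values thus carried this curve as deposited; how it was made and its target are not given in the sources used here. Whether the channel holds RNA of the DOI-treated or of the saline-treated mice is not given either, nor whether the kind is the same on every array.

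For this reason the comparisons of DOI with saline that had been planned, at each dose and over both, were not made, nor was the shift of gene lists against saline. The comparison made was arrays at 10 mg/kg against arrays at 2 mg/kg, on log2 intensity in place of the planned log2 ratio. If the channel holds DOI RNA on every array, the difference is one between doses. If it holds saline RNA on every array, the difference is one between groups of control mice. If it holds DOI RNA on some arrays and saline RNA on others, the difference is neither. The sign, 10 mg/kg minus 2 mg/kg, is known in each case.

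The 3168 spots formed 1056 triplets of 1 clone each. The platform annotation gave exactly 1 gene symbol for 669 clones (604 different symbols, all 669 Entrez identifiers found in the GRCm38.p6 gene table), several symbols for 32, and 355 are unnamed here. Values were turned to log2, averaged over the 3 spots, and centred on each array's median. A clone needed a value on at least 3 arrays at 2 mg/kg and 2 at 10 mg/kg, and all 1056 met this. The fit was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) with 1 coefficient per dose, two-sided, with Benjamini-Hochberg adjustment over the 1056 clones and a threshold of 0.05. No background signal was given, so signal over background could not be computed, and the number of arrays limits the precision. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

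Before the data were examined, 19 gene lists were fixed. Values were averaged per gene for them, and the lists with 5 or more measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative. A list gene counted as measured only where a clone carried its symbol alone. Genes on clones with several symbols, such as Gapdh, or on unnamed clones were not counted. The mean of every list was also compared between doses by an exact two-sided permutation test over the 35 splits of the arrays, for which 0.0286 is the smallest p possible. The rule for named genes, fixed at the same time, took up to 5 clones in each direction past the threshold with doses not overlapping or, as none passed, the 3 with the smallest p in each direction as values, in both cases among clones with exactly 1 gene symbol. It also took every measured immediate early transcription factor, Htr2a, and up to 4 members of each other list by p.

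The fit was tested on simulated data with the means and spreads of the 1056 clones. Of clones changed 2-fold, 43.2% passed the adjusted threshold; the share was 84.9% at 4-fold, 96.3% at 8-fold and 98.6% at 16-fold, and 0.835% of unchanged clones passed. A list of 16 genes was called in 4% of simulations with no shift. The simulation held no separate slide series effect and no correlation between genes. Each run changed 50 clones at each size, which eases the adjusted threshold for all of them. How far the shares of changed clones that passed hold for the real arrays was not tested.

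Alternatives covered centring, scaling between arrays, filters on missing or dim clones, robust variance, array weights, gene averages, an exact permutation test per clone, the slide series as a block or restricted to the second series, leaving out the 20 µg array, leaving out each array in turn, and other thresholds. Added after the data were seen were undoing the authors' curve on 875 clones, removing a trend along the table, and the second slide series with quantile normalization. Lists of circadian clock, tyrosine phosphatase, ubiquitin, GATA, and anion channel and glycolysis genes were also made after the values were seen.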

Results

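Expression in mouse somatosensory cortex was measured 1 h after injection on 7 cDNA arrays, 4 with a DOI dose of 2 mg/kg and 3 with a dose of 10 mg/kg. The median spot intensity lay between 324 on 2 mg/kg replicate 4 and 616 on 2 mg/kg replicate 3. Between 2.08% and 4.80% of the 3168 spots had no value on an array. Such spots were dim: measured spots of the same clones had a median log10 intensity of 1.30, against 2.66 for all values. The median SD between the 3 spots of a clone was 0.168 to 0.282 on the log2 scale. Correlations between arrays ranged from r = 0.864 to r = 0.948, so no array was a copy of another. All values below come from a single channel of each array, and which mouse of the pair it measured is not given. The p values treat the arrays as independent; the titles of 6 of the 7 arrays share a letter with another array, and if these letters name animals, the p values do not hold as given.

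The arrays separated first by slide series. The first principal component held 41.3% of the variance over 1024 clones. It set 2 mg/kg replicates 1 and 2, the arrays of the first slide series, at -16.4 and -20.5. The other 5 arrays lay between 5.02 and 11.4. Those 2 arrays also had the widest spread, with a median absolute deviation (log2) of 2.47 and 2.54, against 1.88 to 2.11 on the others. The arrays were centred but not scaled. A wider spread at 2 mg/kg can by itself set bright clones lower and dim clones higher at 10 mg/kg. Between the slide series, 114 clones passed the adjusted threshold in limma over all 7 arrays, and 1 passed within the 4 arrays at 2 mg/kg, where 208 had an unadjusted p under 0.05. All 3 arrays at 10 mg/kg belonged to the second series.

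**Figure D1:**
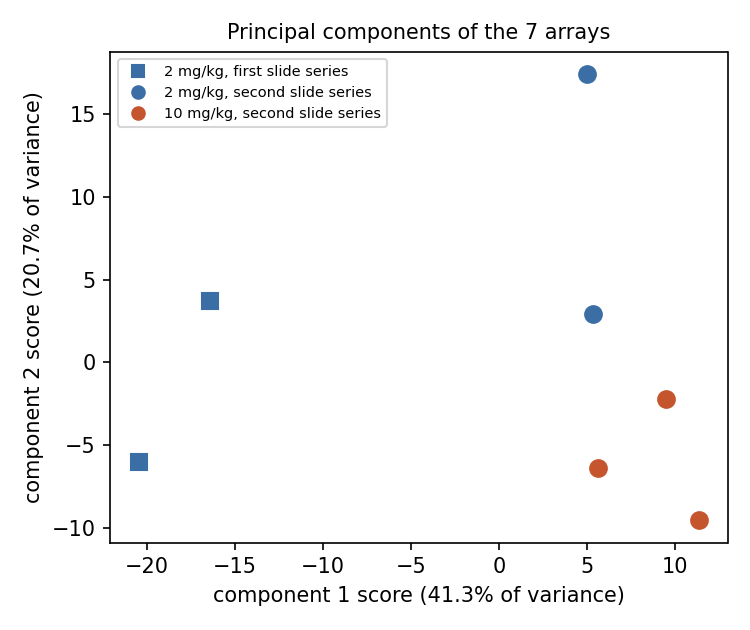
Scores of the 7 arrays on the first (x, 41.3% of variance) and second (y, 20.7%) principal components of centred log2 intensity; each point is 1 array, coloured by dose and shaped by slide series. The 2 squares, both at 2 mg/kg, lie below -16 on x and the other 5 arrays above 5.

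The comparison of 10 with 2 mg/kg asked which transcripts differed with the dose given to the DOI mouse of the pair. No clone passed the adjusted threshold, and the differences that follow are values, not changes. If the measured channel holds saline RNA on every array, they are differences between groups of control mice. If the kind of RNA varies between arrays, they are differences neither between doses nor between control mice alone. Among clones with exactly 1 gene symbol, the smallest p values for a higher level at 10 mg/kg belonged to Rtl8a, a gene derived from a retrotransposon, to Ptpn11, a tyrosine phosphatase of growth factor signalling, and to Tom1l2, which acts in endosomal trafficking. Rtl8a had a log2 level relative to the array median of -0.02 ± 0.69 (SD, n = 4) at 2 mg/kg and 1.43 ± 0.10 (SD, n = 3) at 10 mg/kg, a 2.73-fold difference. Ptpn11 was 2.75-fold and Tom1l2 2.16-fold higher, with log2 differences of 1.46 (SE 0.43) and 1.11 (SE 0.33).

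In the other direction, by the same rule, stood Fen1, an endonuclease of DNA replication and repair, Gria1, an AMPA-type glutamate receptor subunit, and Kcns3, a potassium channel subunit. The level of Gria1 was 2.06 ± 0.24 (SD, n = 4) at 2 mg/kg and 0.61 ± 0.77 (SD, n = 3) at 10 mg/kg, 2.74-fold higher at the low dose. Fen1 was 2.36-fold and Kcns3 2.10-fold higher at the low dose, with log2 differences of -1.24 (SE 0.29) and -1.07 (SE 0.28). The arrays of the doses did not overlap for any of these 6 genes, and all 6 had an adjusted p of 0.293 in limma. The genes were picked by p on the same arrays, which favours doses that do not overlap. Over the table, the doses did not overlap for 14.2% of clones. Clones without exactly 1 symbol were passed over: 4 had a smaller p than Tom1l2 among those higher, and 7 a smaller p than Kcns3 among those lower. Within the second slide series the differences were 0.89 for Rtl8a, 1.26 for Ptpn11, 0.74 for Tom1l2, -1.12 for Fen1, -1.26 for Gria1 and -1.11 for Kcns3. With a trend along the table removed they were 1.02, 0.71, 0.64, -0.65, -1.13 and -0.63 in the same order, so those of Ptpn11, Tom1l2, Fen1 and Kcns3 shrank by over 1.5 times. Quantile normalization, which gives the arrays the same spread, gave 1.56, 1.48, 0.97, -1.06, -1.24 and -0.74 in that order. Of 69 named clones, 36 shrank by over 1.5 times or changed sign within the second series, and 38 did with the trend removed.

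**Figure D2:**
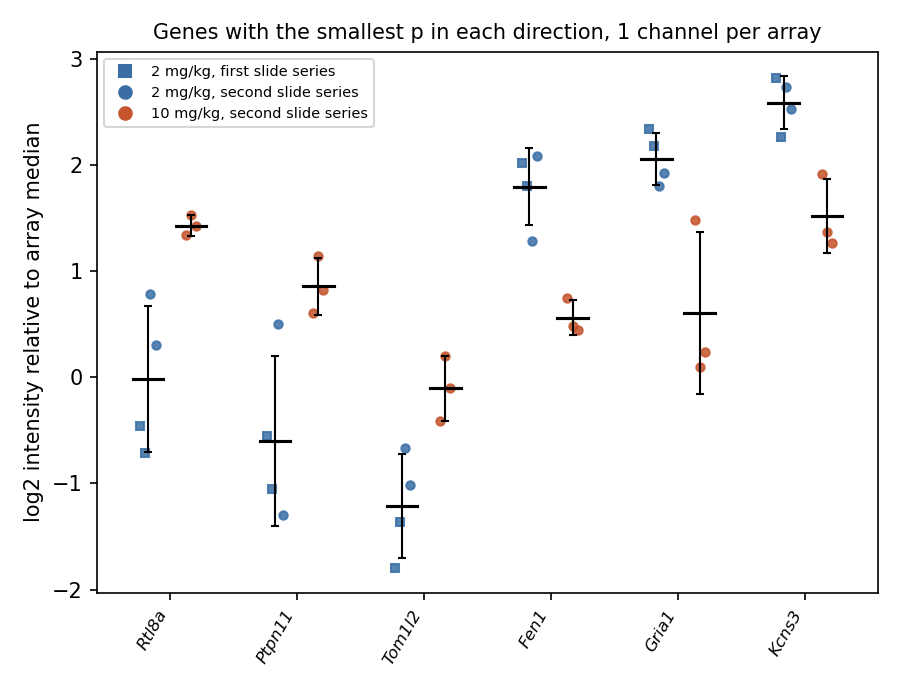
Centred log2 intensity (y, relative to the array median) of the 6 genes with the smallest p among clones with exactly 1 symbol, 3 in each direction (x); points are arrays, bars the mean and SD per dose. Rtl8a, Ptpn11 and Tom1l2 lie higher at 10 mg/kg and Fen1, Gria1 and Kcns3 lower, with an adjusted p of 0.293 in limma for each. The doses do not overlap, which the choice of genes by p favours.

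Over the table, limma gave 0 of 1056 clones with an adjusted p under 0.05 and 160 with an unadjusted p under 0.05, where 52.8 are expected by chance; 66 of the 160 were higher and 94 lower at 10 mg/kg. The exact permutation test per clone gave 52 of 1024 clones at its smallest possible p, 0.0286, the only p under 0.05 it can give, where chance gives 29.3. It gave 0 adjusted calls, but any such call would need 586 clones at that p, so this 0 tells nothing. With no centring of the arrays the split turned to 61 higher and 31 lower, and the median log2 difference of all clones moved from -0.08 to 0.14. With slide series as a block the split was 26 higher and 91 lower, and within the second series 24 and 91. The doses did not overlap for 150 clones, 14.2% of the table, against 5.71% by chance. The median 95% interval reached 0.77 either side on the log2 scale, a 1.7-fold difference, and for 32.2% of clones the interval lay inside a 2-fold difference either way.

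The immediate early transcription factors, genes induced within minutes to hours of neuronal activity, numbered 16 among the measured genes, of which 11 were higher and 5 lower at 10 mg/kg and 0 passed the test, over all genes or adjusted over the list alone. Their mean differed by 0.22 (95% interval -0.11 to 0.55; exact permutation p = 0.2; camera p = 0.117, adjusted 0.649) and by 0.22 within the second series (exact permutation p = 0.3). Fosl2 had a difference of 1.10 (SE 0.62), Junb of 0.95 (SE 0.46), Egr2 of 0.50 (SE 0.33) and Jun of 0.41 (SE 0.30). Fosl2 and Egr4 were dim, with mean levels of -2.91 and -2.92 at 2 mg/kg, and Btg2 was bright, at 6.63. Fos, a common marker of neuronal activity, stood at -0.90 ± 0.67 (SD, n = 4) at 2 mg/kg and -0.64 ± 0.06 (SD, n = 3) at 10 mg/kg. Btg2 (-0.40), Nr4a1 (-0.32), Egr1 (-0.10) and Atf3 (-0.02) were lower at 10 mg/kg, and Jund (0.38), Fosl1 (0.28), Ier2 (0.22), Klf4 (0.18), Egr4 (0.15) and Per1 (0.08) higher. The clones of Myc differed in sign, at -0.63 and 0.32. The differences of Fos, Egr1, Egr4, Nr4a1, Per1, Atf3 and the second Myc clone changed sign under at least 3 alternatives. That of Btg2 changed sign under 1, to 0.72 with arrays scaled to the same median absolute deviation, so its direction depended on the scaling. In the second series Fosl2 came to 0.21, Junb to 0.41, Egr2 to 0.14, Jund to 1.23 and Fos to -0.27. With the trend along the table removed Junb was at 0.48 and Egr2 at 0.04. Both lie between triplets 886 and 905 with other activity-induced genes, so a dose difference shared there would be removed with the trend.

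**Figure D3:**
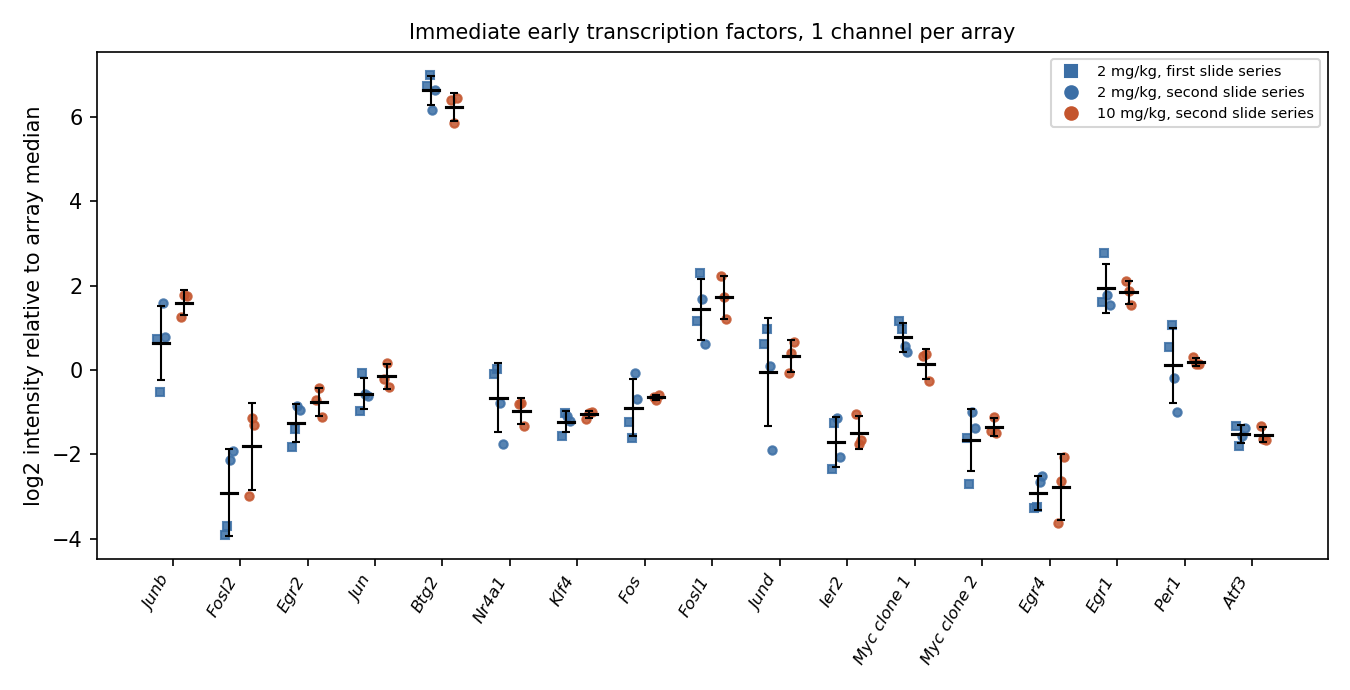
Centred log2 intensity (y) of each measured immediate early transcription factor (x); points are arrays, coloured by dose and shaped by slide series, and bars give the mean and SD. The doses overlap for Fos, Egr1 and Junb, and for Fosl2 the 2 lowest arrays at 2 mg/kg are those of the first slide series.

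The early effectors of neuronal activity had 9 measured genes, 3 higher and 6 lower, with a mean difference of 0.06, a median of -0.02 and an exact permutation p of 0.8. Dusp2, a phosphatase of MAP kinases, differed by 0.78 (SE 0.61) and the growth arrest gene Gadd45g by 0.74 (SE 0.50). Within the second series both were near 0, at 0.05 and 0.00, and a single array of the first series, at -4.53 on 2 mg/kg replicate 1, carried much of the difference of Dusp2. Dusp1 (-0.43), the small GTPase gene Gem (-0.33), Rgs2 (0.09) and Nfkbia (-0.01) completed the named members. The list mean was -0.27 within the second series (exact permutation p = 0.1, the smallest possible) and -0.09 with arrays scaled to the same median absolute deviation. Glucocorticoid-induced genes had 3 measured members with a mean of -0.01 (exact permutation p = 0.914) that was above 0 under the other 3 scalings, among them the glutamine synthetase gene Glul at -0.12.

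Heat shock genes and chaperones were measured for 7 genes, 1 higher and 6 lower, with a mean of -0.18 (exact permutation p = 0.486). Hspb1 (-0.48), both clones of Dnajb1 (-0.27 and -0.48) and Hspa4 (0.30) were among them, and the 3 clones of Dnaja1 stood at -0.26, 0.50 and -1.48, so that clones of this gene did not give 1 answer. Cytosolic ribosomal proteins (6 genes) had a mean of -0.14 (exact permutation p = 0.457), with Rps9 at -0.82 (SE 0.29), Rps15 at 0.59 (SE 0.33), Rpl7 at -0.11 and -0.39 and Rpl37a at -0.20. Genes of oxidative phosphorylation (13 genes) had a mean of -0.04 (exact permutation p = 0.8), with Atp5k at 0.70, Cox5b at 0.48, Cox8a at 0.46 and Sdha at -0.49. Within the second series Atp5k came to 0.31 and Sdha to -0.22, and with the trend along the table removed Atp5k came to 0.17, Cox5b to -0.01 and Sdha to -0.24. Housekeeping genes (9 genes) had a mean of -0.20 (exact permutation p = 0.4). In that list the elongation factor gene Eef1a1 differed by -0.80 (SE 0.24), and Hprt by -0.50. Eef1a1 was bright, with a mean level of 4.87 at 2 mg/kg. Its difference was -0.06 with arrays scaled to the same median absolute deviation. It was -0.58 with quantile normalization and -0.85 within the second series. The actin gene Actb stood at 0.85 (SE 0.38), and the clones of Ldha at -0.40 and -1.17 (-0.09 and -0.47 within the second series, -0.12 and -0.73 with the trend along the table removed). With that trend removed Rps9 came to -0.33, Rps15 to 0.36, Eef1a1 to -0.40, Hprt to -0.25 and Actb to 0.20, and within the second series Actb came to 0.56. The signs of the heat shock, ribosomal, oxidative phosphorylation and housekeeping means changed under 3, 3, 7 and 3 of the 15 alternatives.

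Signalling genes downstream of G protein-coupled receptors had 6 measured members, 4 higher and 2 lower, with a mean of 0.14 (exact permutation p = 0.543) that came to -0.13 once a trend along the table was removed. Grk5, a kinase that desensitises such receptors, was 1.92-fold higher at 10 mg/kg, with a log2 difference of 0.94 (SE 0.32), an adjusted p of 0.293 in limma. The difference was 0.61 within the second series and 0.14 with the trend along the table removed. Prkcd (-0.15), Gnai3 (-0.20) and Rgs2 (0.09) were near 0. No clone was named for Htr2a, the gene of the 5-HT2A receptor, and 0 of the 32 genes in the list of serotonin and monoamine receptors and transporters were measured. Gria1 and the syntaxin gene Stx1a, at -0.55 (SE 0.27), were the 2 measured genes of the synaptic list. Their mean was 1.67 ± 0.15 (SD, n = 4) at 2 mg/kg and 0.67 ± 0.49 (SD, n = 3) at 10 mg/kg (95% interval of the difference -1.66 to -0.35), with an exact permutation p of 0.0286, the smallest possible (0.457 adjusted over the 16 lists with a measured gene), and Gria1 was past the threshold adjusted over the list alone (0.00712) but not over all genes. Within the second series the list mean was -0.94 (exact permutation p = 0.2, where 0.1 is the smallest possible).

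Of the 7 lists with 5 or more measured genes, 0 passed camera (smallest adjusted p = 0.649, and 0.970 with an estimated correlation), and their smallest exact permutation p was 0.2. Markers of cell types were thinly covered. Astrocyte markers (4 genes, all lower) had a mean of -0.34 (exact permutation p = 0.114). Among them were the glutamate transporter gene Slc1a3 at -0.53, Fgfr3 at -0.41 and the gap junction gene Gja1 at -0.32. Fgfr3 was dim, with a mean level of -3.15 at 2 mg/kg. The list mean was -0.30 within the second series, where Gja1 came to 0.15. With the trend along the table removed the list mean was -0.47 and Gja1 came to -0.87. Endothelial markers (2 genes) had a mean of -0.49 (exact permutation p = 0.0857), from the glucose transporter gene Slc2a1 at -0.67 and the cadherin gene Cdh5 at -0.31. That mean was -0.61 within the second series and -0.06 with the trend removed. Striatal and other subcortical markers (3 genes) had a mean of 0.44 (exact permutation p = 0.143), led by the tyrosine hydroxylase gene Th at 1.13 (SE 0.42), with Penk at 0.35. Within the second series Th came to 0.49 and Penk to 0.13, and with the trend removed to 0.72 and 0.10. The list mean was 0.20 within the second series and also with the trend removed. Choroid plexus and meningeal markers (3 genes) had a mean of 0.30 (exact permutation p = 0.2), from Col1a1 (0.40), Igf2 (0.37) and Slc6a13 (0.12), and of 0.09 within the second series and 0.04 with the trend removed. Red blood cell markers (3 genes) had a mean of 0.14 (exact permutation p = 0.714), with Ermap at 0.79, Alas2 at -0.15 and the globin gene Hba-a2 at -0.21. Within the second series the red blood cell mean was -0.31 (exact permutation p = 0.1, the smallest possible), and it was -0.01 with the trend removed. The single excitatory neuron marker was Egr1, whose sign depended on the scaling. Egr1 is also one of the immediate early transcription factors above, so it cannot stand for the content of excitatory neurons alone. The single interneuron marker was Calb1 (-0.39, exact permutation p = 0.114). Calb1 was at -0.40 within the second series, -0.84 with the trend removed and -0.17 without centring. Of oligodendrocyte and microglia markers, 0 were measured.

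**Figure D4:**
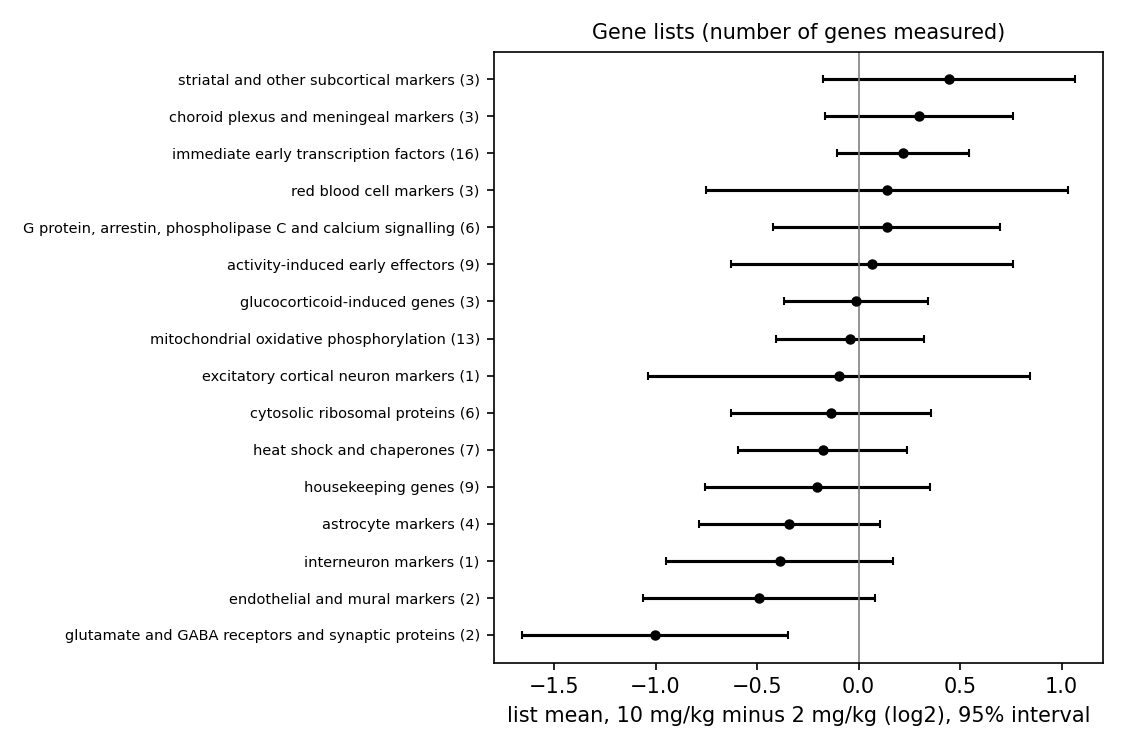
Difference of the list mean between doses (x, 10 mg/kg minus 2 mg/kg, log2) for each list with a measured gene (y, with the number of genes); points are the mean difference over arrays and bars the 95% interval. The interval excludes 0 for the 2 synaptic genes, at -1.66 to -0.35, and includes it for the other lists, immediate early transcription factors among them.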

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

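The tests on slide series, on triplets 2 places apart, on the trend along the table and on the authors' curve were chosen or revised after results were seen, as was the count of splits for the adjusted threshold. Among 85 named clones and list means, 3 had 1 array at 2 mg/kg far from the other 3, where chance gives about 1 in 20. Dusp2 was at -4.53 on replicate 1, with the others between -2.17 and -1.80. The mean of heat shock genes and chaperones was 1.78 on replicate 2, with the others between 1.25 and 1.33. The mean of Gria1 and Stx1a was 1.45 on replicate 3, the 20 µg array, with the others between 1.71 and 1.76. Over the table, 35 of 1036 clones (3.4%) had such an array, and for 15 of these it was replicate 4. No biological explanation was tested for these values.

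The first pattern weighed is the number of clones with an unadjusted p under 0.05, 160 in limma, Rtl8a, Fen1 and Gria1 among them. Of the 35 splits of the arrays into 4 and 3, 2 gave as many, the dose split itself among them, so chance cannot be excluded. The other gave 230, with 28 adjusted calls, and it parted both first-series arrays and 2 mg/kg replicate 4 from the rest. Its group of 3 was thus all at 2 mg/kg, and only 2 mg/kg replicate 3 lay with the arrays at 10 mg/kg. The dose comparison without that replicate gave 220 clones with an unadjusted p under 0.05. This other split followed dose in large part as well as slide series, so as a reference for chance it is not free of dose. Among the splits that keep both first-series arrays in the group of 4, the dose split gave the most, and the next gave 105. These number 10, too few for a share under 0.05. For the adjusted count of 0, 35 of 35 splits gave as many, as any split must. The tables exclude none of the explanations tested. With slide series as a block the count was 117 and 3 of 35 splits gave as many. With the trend along the table removed the count was 101 and 5 of 35 splits gave as many. That trend can hold a dose difference shared by nearby triplets. Many of these 35 splits put first-series arrays in the group of 3, unlike the dose split, so both shares are a poor reference. Within the second series the count was 115 and the highest other of 10 splits gave 79, but 10 splits are too few for a share under 0.05. The authors' curve stays open too, since undoing it on 875 clones gave 118 against 123 with it kept but moved 0 differences by over 1 SE (r = 0.998 across clones), as do a difference between the mice of the dose groups and effects of single arrays.

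The second pattern is that deviations of an array from its dose mean ran along the table. On all 7 arrays, triplets 2 places apart correlated beyond every one of 1000 random orders (r = 0.115 to 0.321 across clones, which are not independent), while on 6 arrays neighbouring triplets stayed inside the random range. A trend shared by every second triplet, as from a printing or hybridisation position, is therefore a candidate explanation. A trend that takes direct neighbours beyond the random range on every array is argued against. On those 6 arrays neighbours correlated at -0.03 to 0.08, so a weaker trend between them stays open. On 10 mg/kg replicate 3 neighbours did correlate beyond the random range (r = 0.179). Triplets 3 places apart correlated at 0.104, 0.123 and 0.106 on the arrays at 10 mg/kg, and at -0.08 to 0.04 at 2 mg/kg. A trend at 10 mg/kg that is not limited to every second triplet stays open. The highest squared rank correlation of deviation with level was 0.081, short of the limit set for a distortion by brightness. Unsquared, this correlation ran from -0.285 to 0.233 over the arrays, similar in size to the correlations along the table. Whether brightness carries part of the trend along the table was not tested. The layout of the arrays was not used here, and no biological explanation was tested.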

How the results depend on the processing

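Undoing the authors' curve, removing the trend along the table, and the second slide series with quantile normalization were chosen after the data were seen. The adjusted count of 0 became 4 with arrays scaled to the same median absolute deviation and 1 in the second slide series alone, and ranged from 0 to 1 over leave-one-out (1 without 2 mg/kg replicate 2). The clones called are unnamed here, lower at 10 mg/kg and dim, at level percentiles 1.2 to 8. The count of 160 at unadjusted p became 92 without centring, 101 with the trend along the table removed, 105 in the second series with quantile normalization and 52 with the exact permutation test, and ranged from 63 (without 10 mg/kg replicate 2) to 220 (without 2 mg/kg replicate 3, the 20 µg array) over leave-one-out. It was 94 without 2 mg/kg replicate 1 and 94 without 10 mg/kg replicate 3. The cause was not tested, except that the permutation test has 35 splits, so that chance gives it 29.3 clones in place of 52.8 and its adjusted count of 0 tells nothing. Undoing the curve moved the differences by a median of 0.04, so its count tells little. The other alternatives stayed within 1.5 times of 160, and the filter on missing values removed nothing, so dropping it says nothing. Quantile normalization gave 83 higher and 81 lower, and the trend removed gave 52 and 49, against 66 and 94. No list passed camera in any alternative run. Of 69 named clones, 0 passed the adjusted threshold in any alternative and 28 changed sign in at least 1; of their 1476 alternative values, 110 had the other sign. The difference of immediate early transcription factors lay between 0.15 and 0.44 and kept its sign in all 15 alternatives. No paired analysis was possible because no pairing of arrays is given: replicate numbers follow accession order, and the letters that recur in the array titles are not explained. Slide series was fitted as a block. Alternatives planned for DOI against saline were not run, since the table holds 1 channel.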

Other observations

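The gene lists of this part, and the tests on the spread of immediate early genes and on clock genes, were chosen only after the values were seen, as were the limits for immediate early genes against dose, whose list and permutation test had been fixed before. The circadian genes Clock and Bhlhe40 were 2.24-fold and 2.78-fold higher at 2 mg/kg, with log2 differences of -1.17 (SE 0.31) and -1.47 (SE 0.41) and an adjusted p of 0.288 in limma over genes. Voltage-dependent anion channel genes Vdac2 (-1.85, SE 0.64) and Vdac3 (-1.02, SE 0.30), the phosphofructokinase gene Pfkl (-0.92, SE 0.35) and Slc2a1 (-0.67) were also lower at 10 mg/kg. A list of 8 such anion channel and glycolysis genes had 7 lower and a mean of -0.73 (exact permutation p = 0.0286, 0.0714 adjusted over 5 lists; camera p = 0.00155, and p = 0.0233 with an estimated correlation). That list was put together from genes already seen to be low, so these p values are no evidence of its direction; its mean was -0.63 within the second slide series and -0.37 with the trend along the table removed. A clone annotated to both Gapdh and Gm5523, at 0.27, was not counted in it. With that trend removed Clock came to -0.74, Bhlhe40 to -1.39, Vdac2 to -1.20, Vdac3 to -0.42, Pfkl to -0.65 and Slc2a1 to -0.23. Of 16 ubiquitin genes, 11 were lower, with Ube2h at -0.85 (SE 0.28). The list mean was -0.16 (exact permutation p = 0.0286, 0.0714 adjusted; camera p = 0.294, and p = 0.312 with an estimated correlation). Under the 3 other scalings it lay above 0, at 0.06, 0.05 and 0.02. Of 13 protein tyrosine phosphatase genes, 7 were higher and 6 lower, with a mean of 0.21 (exact permutation p = 0.2), Ptpn11 at 1.46 (0.71 with the trend removed) and Ptpn2 at -1.37. The 5 GATA transcription factors had a mean of -0.01 (exact permutation p = 0.943), which was 0.21 without centring. The signs of the other means and genes given here were the same under those scalings.

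It was asked as a hypothesis whether clock genes are lower at 10 mg/kg as a group. The 7 measured members had a mean of -0.30 (95% interval -0.66 to 0.05; exact permutation p = 0.114) and of -0.17 within the second slide series. That mean includes Clock and Bhlhe40, which prompted the question. The 5 other genes (Per1, Per3, Cry1, Cry2 and Timeless) lay between 0.01 and 0.20, each within 1 SE of 0. The mean of these 5 was 0.11 (95% interval -0.35 to 0.56). Clones differed in sign for Timeless (-0.76 and 1.04) and Cry2 (0.48 and -0.28). A shift of the whole group is neither favoured nor excluded.

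Another hypothesis was that the channel holds RNA of the DOI-treated mice and that immediate early transcription factors rise with dose. The exact permutation p of 0.2, with an upper 95% limit of 0.55 on the list mean, neither favours nor excludes it, and the identity of the channel stays open. A last hypothesis was that these genes may vary more between arrays of 1 dose than genes of like brightness. Their median residual SD, 0.522 on the log2 scale, was at percentile 96.7 of 10000 random lists of 16 genes matched on brightness, short of the limit set for the test, and at percentile 60.5 within the second slide series. Over all clones the median SD was 0.488 at 2 mg/kg, where both slide series lie, and 0.288 at 10 mg/kg.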
